A study of Nomascus leucogenys with 4 samples.

How the data were processed

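Each of 2 gibbon lymphoblastoid lines gave 1 PU.1 ChIP and 1 input library. Per the labels' protocols, fixed cells were sonicated, immunoprecipitated with an anti-PU.1 antibody on protein A/G beads, and libraries were built with a kit for Illumina sequencing. Groups were taken from the sample titles, and replicate 1 and replicate 2 are names given in accession order. The ChIP and input of one individual belong together by the individual's name in the title.

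The submitters' processing notes list FastQC, Trimmomatic, Bowtie2, SAMtools, MACS2 and edgeR. Per the file headers, the alignments given to the peak caller were trimmed, made with bwa and filtered at a mapping quality of 30, so the aligner differs between headers and notes. Fragments in repeats that map to several places are then largely removed from the peak lists. Per the file headers, peaks were called with MACS 2.1.1.20160309 in paired-end mode, each ChIP library against the same individual's input, with an effective genome size of 2.7 Gb, a q threshold of 0.05, and at most 1 duplicate fragment kept. Replicates were not pooled. Total ChIP fragments before duplicate removal were 46379230 in replicate 1 and 49146146 in replicate 2 (redundant shares 14% and 13%), and total input fragments 34988743 and 44950117 (11% and 10%). The genome build is not given in the sources used here. The peak lists name 26 placed chromosomes and 622 unplaced sequences. Unplaced here means a name that contains Un or random, including names that also carry a chromosome.

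The peak files hold, as deposited by the authors, a fold enrichment ratio per peak over the local background, −log10 p and −log10 q values, and the fragment pileup (coverage) at the summit. The pileups are whole numbers in 100% of peaks. These are the authors' values for each peak and were used to describe, rank and filter peaks. The background at each summit was computed from them as (pileup + 1)/fold enrichment − 1. It lay within 0.01 fragments of its common lowest level in 61.7% of replicate 1 and 59.9% of replicate 2 peaks, the level used here as the genome-wide background. High background means more than 2 times that level.

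The repeat family table deposited by the authors gives a log2 fold change, an average log2 abundance in CPM (counts scaled to library size), a likelihood ratio score, a p-value and an adjusted p-value (FDR) for each of 58 families. A further column deposited by the authors is −log10 of the FDR. Which libraries entered, the model and the repeat annotation are not given in the sources used here. The p-values equal the chi-square tail of the likelihood ratio with 1 degree of freedom, and the FDR equals their Benjamini-Hochberg adjustment. A standard error was computed as the size of the log2 fold change over the square root of the likelihood ratio. Abundances sum to 587484 CPM. Families were assigned to 8 repeat classes from their names.

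Peaks were called shared when they overlapped by at least 1 bp. Chance overlap came from 1000 random placements of the other list, each peak kept on its sequence and at its width. Sequence ends were set at the highest peak end of either list. Matched pairs kept the strongest overlapping peak. Fold enrichment of shared and unshared peaks was compared by a two-sided permutation test of the rank sum (100000 resamples). Proportions carry exact Clopper-Pearson 95% intervals and fragment numbers exact Poisson 95% intervals, which cover counting error only. Fisher's exact tests were two-sided. The family table had no counts per library, so the test chosen for that case was used: Fisher's exact test per class on the authors' calls. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.

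The overlap test was tested on simulated data before use. With the 7133 replicate 2 peaks redrawn, planted shares of 25% and 75% on replicate 1 peaks were measured as 25.6% and 75.2% (permutation p = 0.005 for each, the smallest the placements drawn can give), and a planted share of 0% as 0.687% (permutation p = 0.851).

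The peaks named are the 10 on placed chromosomes with the highest geometric mean fold enrichment in both individuals, and the 3 strongest found in one individual only, for each individual. The families named are those with LAVA or SVA in the name and the 10 with the largest rise and fall among those past an adjusted p of 0.05. A few other families of the same classes were named after their values were seen. This rule, the tests and most alternatives were fixed before the data were examined. The alternatives were a reciprocal overlap of 50%, summits within 100 bp, a −log10 q or fold enrichment of at least 10, equal list lengths, placement within 50 kb, one-to-one pairs, −log10 q in place of fold enrichment, an adjusted p of 0.01, a 2-fold minimum, and a log2 abundance of at least 5. The comparisons of chromosome X and of unplaced sequences, the restriction to placed chromosomes and the centring of family fold changes were added after the data were seen.

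Tests that need a genome or an annotation on the coordinates of the peaks were not run: gene starts, 11 gene lists fixed beforehand, sequence motifs and soft-masked repeats at peak centres. The gene table used here is of the assembly Asia_NLE_v1. Whether the peak coordinates are of that assembly is not given in the sources used here, and peaks lie beyond its last gene on 24 of the 26 chromosome names in both, so its coordinates were not used.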

Results

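Binding of PU.1 was mapped by chromatin immunoprecipitation sequencing (ChIP-seq) in lymphoblastoid cell lines of the northern white-cheeked gibbon, Nomascus leucogenys. Lymphoblastoid lines are B lymphocytes immortalised with Epstein-Barr virus. PU.1, encoded by SPI1, is an ETS-family transcription factor of the B-cell and myeloid lineages. Lines from 2 individuals were used, each with 1 PU.1 ChIP library and 1 input library of unenriched chromatin, giving 4 libraries. The individuals, named Ricky and Vok in the sample titles, are called replicate 1 and replicate 2 here, and the design text describes them as biological replicates. After removal of duplicates, replicate 1 held 39743757 ChIP and 31218578 input fragments, and replicate 2 held 42905332 ChIP and 40288483 input fragments. Peaks were called separately in each individual against its own input, and a single table compares repeat families, with the libraries that entered it not given in the sources used here.

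The first question was how far the PU.1 sites of the 2 individuals coincide. The PU.1 ChIP gave 12399 called peaks in replicate 1 and 7133 in replicate 2, although replicate 2 had 1.08 times as many ChIP fragments. Whether each called peak is a site bound by PU.1 was not tested. Of the replicate 2 peaks, 5605 (78.6%, exact Clopper-Pearson 95% interval 77.6% to 79.5%) overlapped a replicate 1 peak by at least 1 bp. In the other direction 5596 replicate 1 peaks (45.1%, interval 44.3% to 46.0%) overlapped a replicate 2 peak. Random placement of the other list on the same sequences gave 0.655% ± 0.0849 (SD, 1000 placements) for replicate 2 and 0.375% ± 0.0480 for replicate 1. Placement within 50 kb of each peak's own position gave 2.75% ± 0.170 and 1.57% ± 0.0964. The one-sided permutation p was 0.001 in both directions, the smallest that 1000 placements can give. The intervals cover counting error only, and PCR-amplified fragments are not independent molecules. When the longer list was reduced to the 7133 peaks with the best q, 69.2% of the replicate 1 peaks and 69.3% of the replicate 2 peaks were shared.

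The sites missing from the other individual were weaker as a group, though in replicate 1 they also included peaks of middling strength. In replicate 1 the median fold enrichment over background, a value of the authors' peak caller as are all peak values here, was 10.4 (quartiles 6.69 and 18.5) at shared peaks and 4.62 (3.74 and 5.77) at the 6803 unshared peaks. In replicate 2 it was 6.57 (4.87 and 10.7) at shared peaks and 3.49 (2.85 and 4.10) at the 1528 unshared peaks. Both differences had a two-sided permutation p of 1e-05, the smallest that 100000 resamples of the rank sum can give. These p-values are across peaks, which are not independent replicates. A shared peak is also by definition a peak that passed the caller in the other individual. When peaks were ranked by fold enrichment into 10 groups, recovery was 10.9% in the weakest and 98.9% in the strongest group of replicate 1, and 24.2% and 99.7% in those of replicate 2. Counted from the weakest, groups 7 and 8 had recoveries of 55.8% and 79.3% in replicate 1, and of 98.6% and 98.9% in replicate 2. Of the 1278 replicate 1 peaks with a fold enrichment of at least 20, 1265 were found in replicate 2, and 556 of the 556 such replicate 2 peaks were found in replicate 1.

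**Figure D1:**
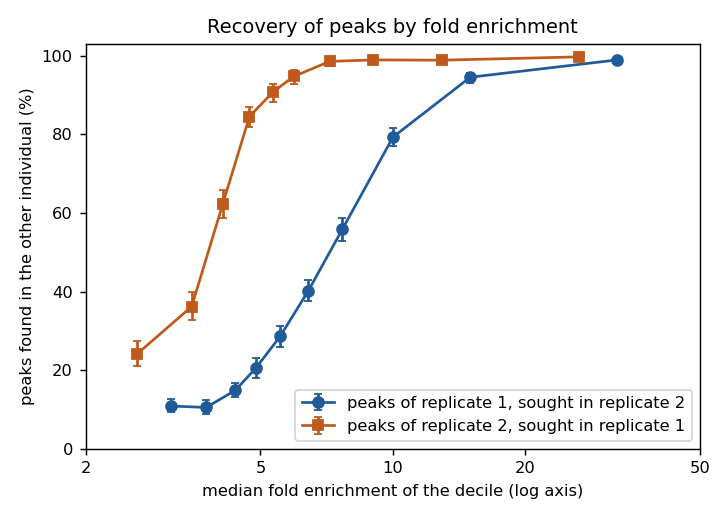
Share of peaks found in the other individual (vertical axis, percent) against the median fold enrichment of each of 10 groups of peaks ranked by fold enrichment (horizontal log axis), with circles for replicate 1, squares for replicate 2 and bars for exact binomial 95% intervals. Recovery lies at 10.9% and 24.2% in the weakest groups and at 98.9% and 99.7% in the strongest.

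At the 5589 matched pairs of shared peaks the individuals ranked sites alike and differed in level. Fold enrichment correlated across peaks with Pearson's r = 0.890 on the log2 scale and Spearman's rho = 0.828. The permutation p was 1e-05 for each, across peaks, which are not independent replicates. Summits lay a median of 8 bp apart, and 93.0% of pairs had summits within 50 bp. Fold enrichment was lower in replicate 2 at 4909 pairs (87.8%), with a median ratio of replicate 2 to replicate 1 of 0.656. The fragment pileup at the summit was also lower in replicate 2, at 4646 pairs, with a median ratio of 0.709. The 2 lists were called separately, and their values were not normalised to each other.

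**Figure D2:**
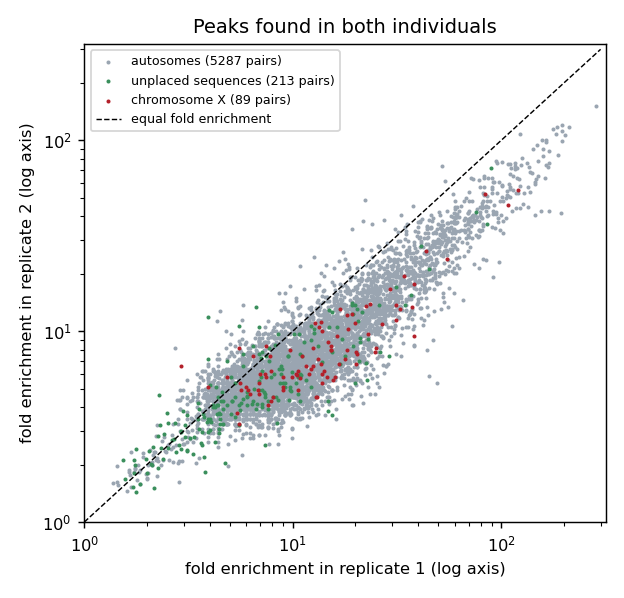
Fold enrichment of each shared peak in replicate 1 (horizontal log axis) and replicate 2 (vertical log axis), coloured by autosomes, unplaced sequences and chromosome X; the dashed line marks equal values. Most points (87.8%) lie below the line, and the highest lies at 285 and 152.

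The 10 strongest shared sites lay on 9 chromosomes and were 840 to 1401 bp wide in replicate 1, against a median of 303 bp for all its peaks. Coordinates are those of the deposited lists, counted from 1, and the genome build is not given in the sources used here. The site with the highest fold enrichment lay on chromosome 12 at 44788630 to 44789620, with 1235 fragments at the summit and a fold enrichment of 285 in replicate 1. In replicate 2 the same site held 820 fragments (fold enrichment 152), with its summit 2 bp away. The next site, on chromosome 19 at 25362122 to 25363118, had fold enrichments of 212 and 117 in replicates 1 and 2. A site on chromosome 25 at 1832894 to 1833875 had 196 and 120, with the same summit base, 1833320, in both individuals. Chromosome 5 held a pair of such sites. The first, at 46875621 to 46876535, had fold enrichments of 196 and 112, and the second, at 55736778 to 55737630, had 196 and 98.9. Sites on chromosome 1a at 59943536 to 59944936 and on chromosome 17 at 37617237 to 37618076 reached 185 and 118, and 202 and 107. Sites on chromosome 14 at 56381355 to 56382265 and on chromosome 2 at 154718769 to 154719710 reached 178 and 114, and 183 and 109. The last of the 10, on chromosome 9 at 23361649 to 23362488, reached 164 and 101. Every one of these 10 sites was higher in replicate 1, and their summits differed by 0 to 3 bp.

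Of the peaks with a fold enrichment of at least 20, 13 in replicate 1 and 0 in replicate 2 lacked a counterpart. The strongest peak found in replicate 1 alone lay on an unplaced chromosome 14 sequence (14_GL397526_1_random, 894927 to 896079), with 260 fragments at the summit (Poisson 95% interval 229 to 294) and a fold enrichment of 60.3. The next ones lay on chromosome 22a at 58784272 to 58784918 (fold enrichment 35.1, 151 fragments) and on chromosome 16 at 65842538 to 65843340 (32.3, 139 fragments). In replicate 2 the strongest unshared peaks were on chromosome 3 at 37732342 to 37732783 (19.5, 94 fragments), chromosome 14 at 7799162 to 7799653 (17.2, 83 fragments) and chromosome 1a at 108629552 to 108630091 (15.8, 76 fragments). The nearest peaks of the other individual were between 8637 and 391685 bp away from these 6 sites.

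The lists also differed in where their peaks lay, a comparison chosen after the data were seen. Chromosome X carried 348 peaks in replicate 1 (2.81% of the list, interval 2.52% to 3.11%) and 101 in replicate 2 (1.42%, interval 1.15% to 1.72%). The ratio of peak numbers, replicate 2 over replicate 1, was 0.290 on X (95% interval 0.230 to 0.363). On the 25 autosomes it ranged only from 0.511 on chromosome 20 to 0.624 on chromosome 23. Relative to autosomal peaks, the odds ratio for X was 0.516 (two-sided Fisher's exact test, p = 1.24e-09, Benjamini-Hochberg adjusted over 2 tests 1.24e-09). With a fold enrichment of at least 10 in both lists the odds ratio was 0.691 and no longer passed Fisher's exact test (p = 0.147). The test compares these lists of peaks, with 1 library per individual, and not populations of animals.

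**Figure D3:**
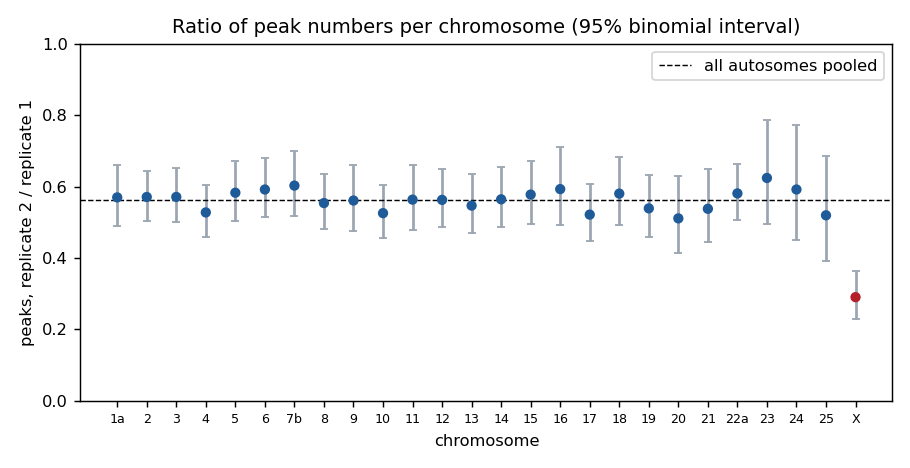
Number of replicate 2 peaks divided by number of replicate 1 peaks (vertical axis) for each placed chromosome (horizontal axis), with exact binomial 95% intervals; the dashed line is the pooled autosomal ratio of 0.563. Chromosome X, at 0.290, lies below every autosome.

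The unplaced sequences, which include some named after a chromosome, behaved in the opposite way. They held 689 replicate 1 peaks (5.56%) and 640 replicate 2 peaks (8.97%), an odds ratio of 1.65 against autosomal peaks (Fisher's exact test, p = 3.19e-18, adjusted p = 6.38e-18). Peaks there were weak, with a median fold enrichment of 3.88 in replicate 1 and 3.13 in replicate 2, against 6.00 and 5.81 on autosomes. In replicate 2, 33.3% of the unplaced peaks (interval 29.6% to 37.1%) were found in replicate 1, against 83.0% of autosomal peaks (82.0% to 83.9%). The unplaced sequences accounted for 27.9% of the replicate 2 peaks missing from replicate 1. The excess ended among peaks with a −log10 q of at least 10, where the odds ratio was 1.06 (Fisher's exact test, p = 0.635). At a fold enrichment of at least 10 it was 0.820 (Fisher's exact test, p = 0.428). With equal list lengths it was 3.27, but only the replicate 1 list was cut there, to its peaks with the best q. That cut takes weak peaks from replicate 1 alone, leaving 207 unplaced peaks against 640 in replicate 2, so the value decides nothing.

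The series asks about retrotransposons, in particular LAVA, a composite element of the gibbon lineage, and the repeat family comparison bears on this. In the authors' deposited table of 58 repeat families, 28 passed an adjusted p of 0.05, 16 of them higher and 12 lower. The file does not state its numerator, so the direction is an assumption: positive values are read here as higher in PU.1 ChIP than in input, and rose and fell are used in that sense. Read the other way, 12 families would be higher and 16 lower. Changes were small: log2 fold changes ran from -0.27 to 0.54, and no family reached a 2-fold change. Centring the fold changes on the abundance-weighted mean of 0.03 turned the split into 13 higher and 24 lower families. Standard errors below are those implied by the table's likelihood ratios. Numbers of libraries and their spread are not in the table, so no SD or n is given.

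SVA, a composite retrotransposon family of apes that shares its tandem repeat core with LAVA, had the smallest adjusted p, 1.52e-59, in the authors' deposited table. Its log2 fold change was 0.40 (SE 0.0245), or 1.32-fold (95% interval 1.28 to 1.37), at an abundance of 889 CPM (counts scaled to library size). No family of the table carries LAVA in its name, so LAVA is not separated from other elements here. Only the family named telo, classed with the satellites, had a larger log2 fold change, 0.54 (SE 0.0386), or 1.45-fold in the authors' deposited table. With the sign turned, the authors' deposited table would give SVA 0.755-fold and telo 0.690-fold, the lowest values in PU.1 ChIP among the families past the threshold.

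All 4 satellite families rose in the authors' deposited table, which 12 of the 54 other families also did. This share passed Fisher's exact test after adjustment over 8 repeat classes (two-sided, adjusted p = 0.0172). Besides telo, they were the acromeric repeats (acro, log2 fold change 0.32, SE 0.0427), Satellite (0.22, SE 0.0239) and the centromeric repeats (centr, 0.19, SE 0.0212). Of 6 structural RNA families, 3 rose: ribosomal rRNA (0.32, SE 0.0220), RNA (0.17, SE 0.0310) and srpRNA (0.10, SE 0.0251), the RNA of the signal recognition particle. The share of structural RNA families that rose did not pass the test (adjusted p = 0.443). With the sign turned, the same 4 satellite families would be the ones lower in PU.1 ChIP, at 0.690-fold to 0.878-fold in the authors' deposited table, with the same test. The 3 structural RNA families would then be lower too, with rRNA at 0.798-fold, RNA at 0.891-fold and srpRNA at 0.932-fold in the authors' deposited table.

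Of 10 LTR families, which derive largely from endogenous retroviruses, 6 rose, 2 fell and 2 were not called. The authors' deposited table gives log2 fold changes of 0.10 for ERVK (SE 0.0194), 0.09 for ERVL, 0.08 for ERVL-MaLR and 0.08 for ERV1. The LTR share did not pass Fisher's exact test (adjusted p = 0.0531), and passed it when families were called at an adjusted p of 0.01 (adjusted p = 0.0359). Over all alternatives that gave a value this adjusted p lay between 0.0359 and 0.299. Among 6 SINE families, short elements copied by the LINE machinery, Alu rose (0.14, SE 0.0210) and so did 5S-Deu-L2 (0.07). MIR, at -0.01, was not called. With the sign turned, 6 LTR families would be lower in PU.1 ChIP and 2 higher, with ERVK at 0.934-fold and Alu at 0.905-fold in the authors' deposited table.

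DNA transposons, which are ancient and inactive in apes, included no family that rose. Of 21 such families, 8 fell and 13 were not called, and 0 had a positive fold change with an unadjusted p under 0.05. The absence of risen families passed Fisher's exact test (adjusted p = 0.00145), whereas the 8 that fell did not stand out after adjustment (adjusted p = 0.160). The test counts calls, which rare families with wide errors seldom reach. Fold changes were positive in 5 DNA families and negative in 16. The positive ones included PiggyBac? (0.08, SE 0.0521) and PIF-Harbinger (0.13, SE 0.378) in the authors' deposited table. The largest falls in the authors' deposited table were those of TcMar (-0.27, SE 0.0650), Helitron? (-0.14, SE 0.0412), TcMar-Tc2 (-0.13, SE 0.0217) and PiggyBac (-0.10, SE 0.0246). DNA? (-0.08), TcMar-Mariner (-0.07) and TcMar-Tigger (-0.07) followed. Among 8 LINE families, RTE-X (-0.08, SE 0.0187) and L1, the main autonomous retrotransposon (-0.07, SE 0.0200), fell, and the other 6 were not called. Centring on the abundance-weighted mean, chosen after the data were seen, gave 13 lower DNA families in place of 8 and 5 lower LINE families in place of 2. Neither share then passed Fisher's exact test (adjusted p = 0.210 and 0.511). LTR? was also lower, at -0.09 (SE 0.0200). With the sign turned, the 8 DNA families would be higher in PU.1 ChIP and none lower, with TcMar at 1.21-fold and Helitron? at 1.10-fold in the authors' deposited table. The LINE families RTE-X and L1 would be higher as well, at 1.05-fold each in the authors' deposited table.

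**Figure D4:**
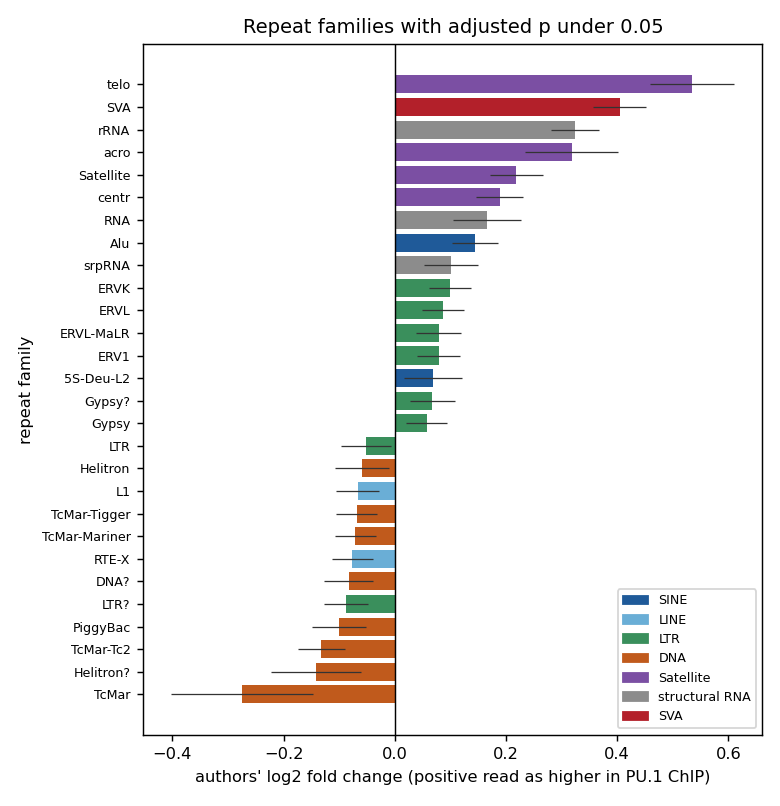
The authors' log2 fold change (horizontal axis, positive read as higher in PU.1 ChIP) for the 28 repeat families (vertical axis) with an adjusted p under 0.05, with bars coloured by repeat class and thin lines for 95% intervals implied by the likelihood ratio. The telo, SVA and rRNA families have the largest positive values (0.54, 0.40 and 0.32) and TcMar the largest negative value (-0.27), and since the numerator is not stated these would be the largest falls and the largest rise with the sign turned.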

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

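The odds ratios, the shares at the background floor, the comparisons at like q and the test of unplaced peaks without high background were chosen after the results were seen, and the other tests before their values were computed.

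A difference between groups drew attention to chromosome X: its share of peaks differed between the 2 individuals, with an odds ratio of 0.516 for replicate 2 against replicate 1. Of the X peaks with a fold enrichment of at least 20 in replicate 1, 22 of 22 were found in replicate 2 (1223 of 1235 on autosomes), and the odds ratio lay nearer to 1 among stronger peaks, at 0.734 for a −log10 q and 0.691 for a fold enrichment of at least 10. Weakness of the replicate 1 X peaks as the whole cause is argued against by their recovery, 25.6% (21.1% to 30.5%) where autosomal peaks of like fold enrichment give 40.1%, and 39.3% at like q. Fewer X copies per cell in replicate 2 remain open, as does a difference in binding on X. At those 22 X peaks, the log2 pileup ratio of replicate 2 to replicate 1 lay -0.37 (bootstrap interval -0.55 to -0.27) from that of autosomes. The interval holds neither 0 nor the -1 predicted for fewer X copies in every cell of replicate 2. That -1 takes every X copy as bound equally, which was not tested, so fewer X copies in every cell are not excluded. At all 89 shared X pairs the median log2 pileup ratio was -0.72, against -0.50 at 5287 autosomal pairs. Such pairs hold only sites called in both individuals, 25.6% of the replicate 1 X peaks and 46.6% of its autosomal peaks. Their gap is therefore not the size of the X difference over all sites. The implied background was at its genome-wide floor for 85.1% of replicate 2 X peaks (76.7% to 91.4%) against 63.5% on its autosomes, and for 66.7% (61.4% to 71.6%) against 63.3% in replicate 1, which is in line with lower X coverage in the replicate 2 input but comes from peaks chosen by the caller.

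The share of peaks on unplaced sequences also differed between the individuals, with an odds ratio of 1.65. Among the stronger peaks the difference did not pass Fisher's exact test, and weak peaks alone were not tested. Weakness alone is argued against by the recovery of unplaced replicate 2 peaks in replicate 1. It was 33.3% (29.6% to 37.1%), where placed peaks of like fold enrichment give 48.9% and of like q 57.1%. Background above 2 times the genome-wide level on the unplaced sequences is argued against as the whole cause. Unplaced peaks without it were recovered at 41.2% (36.0% to 46.4%), against 59.2% for placed peaks without it at like fold enrichment. A milder rise in background is not excluded, since 20.3% of all replicate 2 unplaced peaks lay at the background floor, against 63.5% on autosomes. Whether high background contributes cannot be told apart from peak strength: on placed chromosomes such peaks were recovered at 48.6% (42.1% to 55.0%), above the 40.5% expected at like fold enrichment and below the 64.1% expected at like q. Matching on fold enrichment alone gives high-background peaks more fragments, which is why that bound, set beforehand, decides nothing, and a difference in sequence content between the individuals was not tested.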

How the results depend on the processing

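The comparisons of X and of unplaced sequences, the restriction to placed chromosomes and the centring of family fold changes were added after the data were seen. All 29 alternatives for the overlap, strength and correlation of peaks kept their direction and their side of the threshold, although placement within 50 kb raised the chance overlap to 1.57% of replicate 1 and 2.75% of replicate 2 peaks. For the overlap this was a weak check, since no setting brought the chance overlap near the observed overlap. The shared part ranged from 41.8% to 69.2% of replicate 1 peaks and from 69.3% to 96.4% of replicate 2 peaks, the upper ends under equal list lengths and a fold enrichment of at least 10. Of 30 alternatives for the repeat families, 24 kept their call and stayed within 1.5 times the count. Under a log2 abundance of at least 5, the families left out stayed in the class tests as not called. The class tests of that setting, which are among the 30, are therefore a weak check. A 2-fold minimum left 0 families higher and 0 lower. Centring on the abundance-weighted mean gave 24 lower families in place of 12, with 13 DNA families in place of 8 and 5 LINE families in place of 2, since by construction it moves every fold change down by 0.03. LTR families passed the class test at an adjusted p of 0.01 for calling families (0.0359 in place of 0.0531), and 6 were called in either case. The X difference no longer passed at a fold enrichment of at least 10 (odds ratio 0.691), where 24 replicate 2 X peaks were left, and passed under the other two settings. The unplaced difference no longer passed at a −log10 q of at least 10 (1.06) and turned at a fold enrichment of at least 10 (0.820), with the cause not tested. Leaving out a replicate gives no value, since each comparison of peaks needs both lists and the family table has no libraries. No paired analysis was possible because the table holds no values per library. For the same reason the alternatives of normalisation, of a filter on low counts and of left-out libraries for the families were not run, nor were those of gene starts, gene lists, motifs and repeat masking, which need a genome. Weak sites were the least often shared, with the cause not tested: in the weakest of 10 groups by fold enrichment, 10.9% of replicate 1 and 24.2% of replicate 2 peaks were found in the other individual.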

Other observations

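The densities, the windows and the test of SVA against tandem and ribosomal sequence were chosen after the data were seen. PU.1 peaks were unevenly spread over the chromosomes. Replicate 1 had 5.71 peaks per Mb on chromosome 23 and 3.18 on chromosome 20, and replicate 2 had 3.56 and 1.62 on the same chromosomes, with lengths taken as the highest peak end. Chromosome X was below every autosome in both individuals, at 2.46 and 0.715 peaks per Mb. The densest 100 kb window of a placed chromosome was the same in both individuals, chromosome 6 at 26100001 to 26200000, with 33 peaks in replicate 1 and 30 in replicate 2. All 30 replicate 2 peaks and 31 replicate 1 peaks there were shared, whereas 1000 random placements reached at most 8 and 6 peaks in any window. These peaks were weak, with median fold enrichments of 2.26 and 2.04, and their background was 44.3 and 93.5 times the genome-wide level. The next window of replicate 1, chromosome 1a at 44400001 to 44500000, differed: it held 13 peaks with a median fold enrichment of 17.1 at 1.15 times the genome-wide background.

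A pair of the 13 strong peaks found in replicate 1 alone lay on chromosome 22a within the same region, at 58776567 to 58777129 (fold enrichment 23.1) and at 58784272 to 58784918 (35.1). The nearest replicate 2 peaks were 33850 and 41555 bp away. The background at both was at the genome-wide level.

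The rise of SVA in the repeat family comparison rests on reading positive values as higher in PU.1 ChIP, which the file does not state. A trend with family abundance is argued against, since the line of log2 fold change on log2 abundance over 58 families was almost flat (slope 0.0012, Spearman's rho = 0.086). SVA lay 2.74 residual SDs above that line, which for so flat a line mostly restates that its fold change was large. A candidate explanation that stays open is a rise of tandemly repeated and ribosomal sequence in ChIP libraries that SVA, which carries a tandem repeat core, shares. The 5 satellite and rRNA families had a median log2 fold change of 0.32 (range 0.19 to 0.54), against 0.40 for SVA, and a ChIP with another antibody would be needed to tell this from binding of PU.1 to SVA.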
